A study of Mus musculus with 4 samples.

How the data were processed

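Per the labels' protocols, lethally irradiated C57BL/6 mice received bone marrow of Cd4cre Cd137fl/fl tomato and Cd137fl/fl tomato donors, and B16K1 cells were injected subcutaneously after reconstitution. CD8 T cells of spleen and tumour were isolated with beads on day 21 and sorted by the tomato reporter. Cells of 7 mice were hashtagged and pooled into 4 suspensions, which gave 5' single-cell libraries with the 10x Chromium Single Cell 5' kit v1.1, sequenced on an Illumina NextSeq instrument. The sorting protocol and the series design call tomato-positive cells CD137 minus, whereas the source names call the CD137ko cells tomato negative, so groups were taken from the CD137 status alone. The mixed chimera puts cells of both donors in the same mice, but the table names no mouse and no hashtag per cell.

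Per the submitters' processing notes, Cell Ranger 3.0.2 and Seurat 3.0 were used with the mm10 genome. Parameters, cell filters, normalization and annotation are not given in the sources used here. The deposited table holds 6965 cells and 12763 genes in natural log units, the natural log of 1 plus a whole number, to a relative tolerance of 1e-12 for all entries. The whole numbers were recovered by the exponential. Their totals per cell spanned 3110 to 4884 in spleen CD137 minus, 4096 to 5872 in spleen CD137 plus, 3632 to 5712 in tumour CD137 minus and 2949 to 4588 in tumour CD137 plus. Such narrow ranges are those of counts that the authors corrected to one depth per library, which is read from the values and not stated in the labels, so they are called corrected counts and no count model was used. Genes with a value in fewer than 5 cells of a library are listed at 0 there, apart from 8 genes of the spleen CD137 minus library. The plan allowed ratios of libraries for raw counts or for values with a constant sum, and ratios were taken here from corrected counts scaled to each library's total, a departure from its wording.

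For each library corrected counts were summed over cells and scaled to a total of 1e+06 (CPM). The log2 ratio of 2 libraries was taken with a pseudocount of 1 CPM. A gene was measured in a comparison when it had at least 20 CPM and a value in at least 5% of cells in 1 of the libraries and a value in both. It was called higher or lower when the log2 ratio was at least 0.5 in size. For each comparison the 12 measured genes furthest above and the 12 furthest below 0 were named. Left out were receptor segment, immunoglobulin, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, and unnamed gene models and clone names such as Gm with digits or Rik. Of the genes this rule names, 1 is not reported here. The other examples taken from lists, clusters and states were chosen after their values were seen. The comparisons, the lists, the markers, the filters, the size limit and the rule for named genes were chosen before the data were examined. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on expression, which describes these libraries and is no test.

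Fixed lists covered naive-like, memory-like, effector-like, progenitor exhausted-like, terminally exhausted-like, proliferating-like and interferon-response-like states. Others held tissue residency, inhibitory and costimulatory receptors, cytotoxic effectors, cytokines and chemokines, NF-kB genes, apoptosis regulators, TCR-induced and lineage transcription factors, stress, glycolysis, oxidative phosphorylation, cholesterol synthesis, trafficking, MHC class I, the T cell receptor complex, housekeeping and ribosomal genes, and markers of other cell types. Tnfrsf9 was left out of all lists.

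Cells were clustered jointly on the log of corrected counts per 10000 over 2000 variable genes, without Tnfrsf9, receptor segment, mitochondrial and ribosomal genes, with 30 principal components, 15 neighbours and Leiden resolution 1. A marker of a cluster had a log2 level at least 1 above the mean of the other clusters and a value in 10% of its cells. A cluster was named for the state list with the largest share of markers if it had at least 3 of them, led the next list by more than 0.1 and no other list had more members among the 10 leading genes. These naming thresholds were set after an exploratory clustering of the same cells with another implementation had been looked at. Shares of cells have exact Clopper-Pearson 95% intervals. Within tumour states the contrast was computed where each library held at least 50 cells. For shares of cells with a value, cells were also thinned to 2900 corrected counts. No doublet caller was run, so doublets are not excluded. Copies of genes among annotated processed pseudogenes were counted by alignment with minimap2 2.31, at 90% identity over at least 200 nt.

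Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9 were used, with GENCODE symbols, which matched 12631 of the genes. The procedure was tested on simulated data with 200 genes set to differ by a log2 ratio of 1. It recovered 99.5% of them for the tumour contrast, 98% for the spleen contrast, 99% for tumour against spleen in CD137 plus and 98.5% in CD137 minus cells. Of the genes left alone, 0.0395%, 0.714%, 0.761% and 0.0412% passed the size limit. The simulation holds counting noise and no differences between mice.

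Alternatives were centring on the median log2 ratio, no filter and a filter of 100 CPM, pseudocounts of 10 and 100 CPM, cells with Cd8a or Cd8b1 and without markers of other cells, the mean over cells, a filter on genes and mitochondrial share, leaving out proliferating-like cells, lists matched on the share of cells, and other resolutions, seeds and variable genes. Added after the data were seen were scaling without ribosomal protein genes, thinned cells, leaving out other cell types, the library-dominated cluster or naive-like cells, and more seeds. The hashtag and protein libraries are not analysed here, and receptor segments are used only in a note on Trbv genes.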

Results

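The series measured single-cell transcriptomes of CD8 T cells from mixed bone marrow chimeras, mice in which irradiated recipients received marrow of 2 donors. The first donor carried Cre recombinase under the Cd4 promoter and loxP-flanked Cd137, so that its T cells lose CD137, and the other carried the loxP-flanked gene without Cre. CD137 (4-1BB), encoded by Tnfrsf9, is a costimulatory receptor of activated T cells. The mice bore subcutaneous B16K1 melanomas, derived from the B16 mouse melanoma line, and cells were taken on day 21. CD8 T cells of spleen and tumour were sorted by the tomato reporter, not by CD137 itself, into fractions called CD137 minus and CD137 plus. The cells of 7 mice were pooled into 1 library per fraction, which gave 4 libraries. The donors differ in Cre as well, so an effect of CD137 loss cannot be told apart from one of Cre or of the donor.

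The table held 2464 cells of the spleen CD137 minus library, 473 of spleen CD137 plus, 1262 of tumour CD137 minus and 2766 of tumour CD137 plus. Their corrected counts, defined in the methods, summed to 9829562, 2466601, 6037757 and 10273681. The median corrected total per cell was 3973, 5344, 4833.5 and 3701.5, and the median number of genes per cell 1326.5, 1633, 1432 and 1307.5. Each group was 1 library with no replicate, and cells were not assigned to mice, so no difference below has a test or a replicate error. Values of both libraries are given, with the first-named library of a comparison first. Levels are given as CPM, the corrected counts scaled to a library total of 1e+06, and the third value in parentheses is the log2 ratio with a pseudocount of 1 CPM. Intervals on shares of cells are exact 95% binomial intervals and cover counting error only.

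The deleted gene was examined first. Tnfrsf9 (ENSMUSG00000028965.13) lies on the plus strand of chromosome 4 from 150914562 to 150946102 in mm10, where the GENCODE annotation gives it 9 transcripts with 2 to 8 exons. Its level was 57.5 CPM in the tumour CD137 minus library and 421 CPM in the tumour CD137 plus library, a log2 ratio of -2.85. In spleen it was 2.34 CPM in the minus and 16.2 CPM in the plus library (-2.37), both below the 20 CPM filter on other genes. The spleen ratio rests on 23 and 40 corrected counts and was -1.09 with a pseudocount of 10 CPM and -0.18 with 100 CPM. The share of cells with a Tnfrsf9 value was 15.8% (13.9 to 18.0) in tumour minus and 45.3% (43.4 to 47.1) in tumour plus. In spleen it was 0.852% (0.528 to 1.30) and 4.23% (2.60 to 6.45). After each cell was thinned to 2900 corrected counts, which left out no cell, the shares were 10.8% and 41.8% in tumour and 0.690% and 2.54% in spleen. Raw totals per cell are not in the table, so thinning evens the corrected totals and not the raw depth. In naive-like cells, a class named from markers only, the share was 1.36% in tumour minus and 10.1% in tumour plus, at median totals of 4871.5 and 3862 per cell. In spleen it was 0.471% (0.204 to 0.926) in the minus and 3.14% (1.36 to 6.09) in the plus library, at median totals of 3876 and 5251. Outside naive-like cells it was 1.70% (0.907 to 2.88) in the minus and 5.50% (2.88 to 9.42) in the plus library. The direction goes with the CD137 status in the labels. The labels give the tomato reporter of the minus fraction in contradictory ways, so only CD137 status was used. Which exons were deleted is not given in the sources used here, and a 5' tag can lie outside the deleted part.

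**Figure D1:**
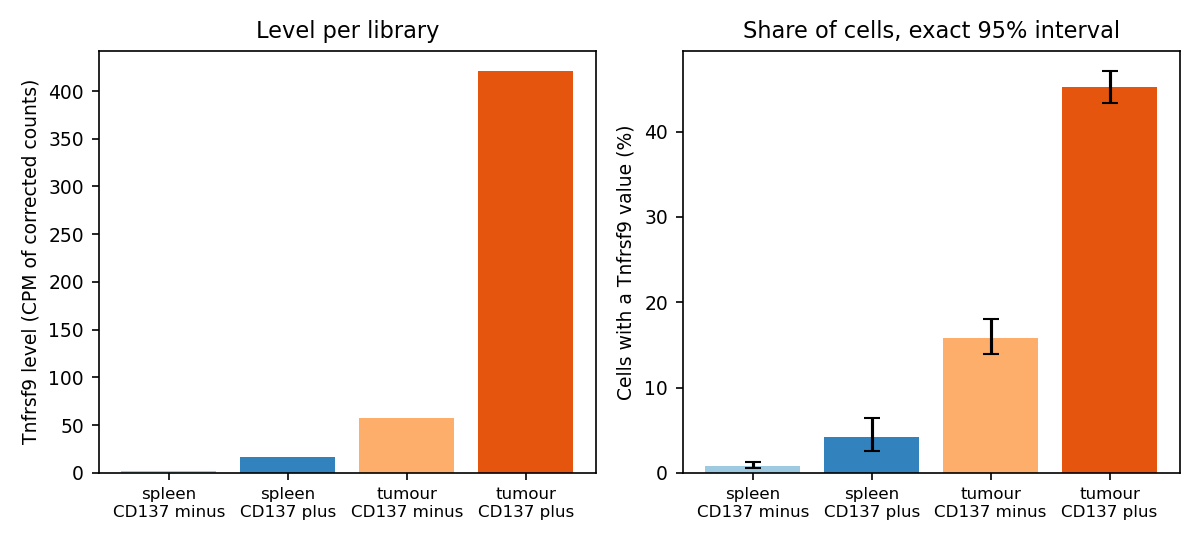
Tnfrsf9 in the 4 libraries. The bars on the left give its level in CPM of corrected counts, and the bars on the right the share of cells with a value in percent, with exact 95% binomial intervals as error bars; the tumour CD137 plus library holds the highest level, 421 CPM, and the highest share, 45.3%.

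The comparison within the tumour asked how tumour-infiltrating CD8 T cells of the CD137 minus fraction differ from CD137 plus cells of the same animals. Part of the naive T cell genes were higher in the tumour CD137 minus library, and part of the exhaustion, cytotoxicity and chemokine genes were lower, by the counts given below. Among the higher were Lef1 (180.4 against 113 CPM, 0.67) and Satb1 (112 against 72.0 CPM, 0.64), transcription factors of naive T cells, and Igfbp4 (101 against 56.9 CPM, 0.81), a marker of naive T cells. Among the lower were Tigit (254 against 412 CPM, -0.70) and Pdcd1 (363 against 518 CPM, -0.51), which encode the inhibitory receptors TIGIT and PD-1, Gzmb (124 against 259 CPM, -1.06), which encodes granzyme B, and the chemokine genes Ccl3 (149 against 392 CPM, -1.39) and Ccl4 (313 against 733 CPM, -1.22). Over the 5353 measured genes the median log2 ratio was -0.13 with an SD over genes of 0.27. This shift is larger than 0.1, so list medians are given as measured and relative to it. Pdcd1 passes the size limit as measured but not once the shift is taken off, and the same holds for each gene given below that lies beyond -0.5 by less than the shift.

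Of the naive-like list, 4 of 10 measured genes were higher by at least 0.5 and 0 were lower, with a median of 0.47 (0.60 relative to all genes). Relative to all genes, 9 of them passed that size, among them Il7r (0.45), which encodes the IL-7 receptor alpha chain, and all but Ccr7 (0.31), a lymph node homing receptor. The progenitor exhausted-like list had a median of 0.25 (0.38 relative), with Id3 (0.58) and Tcf7 (0.38) above 0 and Xcl1 (-0.39) below. It shares Tcf7 and Il7r with the naive-like list. Of the T cell lineage transcription factors, 5 of 15 were higher, among them Bach2 (0.59) and Foxp1 (0.52), and only Tbx21 (-0.71), which encodes the effector factor T-bet, was lower by that size. The median of this list was 0.21 (0.34 relative).

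In the terminally exhausted-like list, 8 of 13 genes were lower by at least 0.5 and 0 were higher, with a median of -0.53 (-0.40 relative), at percentile 0 of 10000 random lists matched on expression. All 13 values were below 0, from Cxcr6 (-0.43) to Gzmb (-1.06). Relative to all genes, 3 of 13 passed the size. Inhibitory receptors had 5 of 11 lower and a median of -0.45 (-0.32 relative), with Klrc1 (-1.12) the lowest and Cd200 (0.13) and Vsir (0.09) above 0. Cytotoxic effectors had 5 of 12 lower and a median of -0.41 (-0.28 relative), among them Gzmk (-0.86), Prf1 (-0.64), which encodes perforin, and Nkg7 (-0.56). In the cytokine and chemokine list 5 of 11 were lower, including Ifng (-0.89), which encodes interferon gamma, and Ccl5 (-0.69), against a median of -0.39 (-0.26 relative). Transcription factors induced by T cell receptor signalling had a median of -0.39 (-0.26 relative), with Nr4a2 (-0.55), Bhlhe40 (-0.52) and Tox (-0.53) lower as measured but short of the size relative to all genes. Several genes stand in more than 1 of these lists, so their medians are not independent.

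Of genes linked to CD137 signalling, 4 of 20 in the NF-kB list were lower and 0 higher, namely Bcl2a1d (-1.28) and Bcl2a1b (-0.55), anti-apoptotic members of the BCL2 family, Birc2 (-0.90) and Nfkb2 (-0.55), while the list median was -0.15 (-0.02 relative). Apoptosis regulators had 3 of 13 lower and a median of -0.30 (-0.17 relative). Costimulatory receptors had a median of -0.20 (-0.07 relative), with Tnfrsf4 (-0.52) and Tnfsf9 (-0.63), the gene of the CD137 ligand, lower by at least 0.5. The proliferating-like list had 5 of 13 lower, including Mcm5 (-0.61), and a median of -0.33 (-0.20 relative), and the cholesterol synthesis list 2 of 8 and -0.34 (-0.21 relative). Glycolysis genes had 3 of 15 lower, Gapdh (-1.15), Eno1 (-0.82) and Pfkp (-0.56), and a median of -0.27 (-0.14 relative). MHC class I presentation genes had a median of -0.30 (-0.17 relative) with Tap1 (-0.65), memory-like genes -0.36 (-0.23 relative), tissue residency genes -0.37 (-0.24 relative) and effector-like genes -0.18 (-0.05 relative). Interferon-response-like genes were at -0.13 (0.01 relative), nuclear oxidative phosphorylation genes at -0.05 (0.08 relative) and dissociation stress genes at -0.03 (0.10 relative), so their sign depends on the shift. Trafficking receptors were at 0.00 (0.13 relative) and the T cell receptor complex with CD8 at -0.22 (-0.09 relative). Housekeeping genes were at -0.26 (-0.13 relative), with Actb (-0.21) and Ppia (-0.17), and cytosolic ribosomal proteins at 0.10 (0.23 relative). Counts of lower genes depend on the shift as well. Relative to all genes they were 2 of 11 inhibitory receptors, 4 of 12 cytotoxic effectors, 4 of 11 cytokines and chemokines, 2 of 20 NF-kB genes, 2 of 13 apoptosis regulators, 1 of 13 proliferating-like genes, 2 of 15 glycolysis genes, 1 of 8 cholesterol synthesis genes, 1 of 11 TCR-induced factors (in place of 4), 1 of 13 MHC class I genes (in place of 3) and 0 of 11 costimulatory receptors.

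By the fixed rule of size, the genes furthest above 0 in the tumour were Smim19 (23.7 against 7.79 CPM, 1.49), Foxk1 (0.96), Hist1h4c (0.91), Tmem108 (0.90), Lmtk2 (0.88), Smim27 (0.86), Scml4 (0.85), Slc43a2 (0.83), Igfbp4 (0.81), Ifngr2 (0.77), Lcn4 (0.73) and Setd5 (0.73). Most of these lay near the level filter. Those furthest below 0 were Tnfrsf9, Erh (37.8 against 102 CPM, -1.41), Ccl3, H2-Aa (35.9 against 94.6 CPM, -1.37), an MHC class II gene, Gsr (-1.31), Ywhaq (49.9 against 124 CPM, -1.30), Bcl2a1d (67.7 against 166 CPM, -1.28), Ccl4, Crbn (34.8 against 81.5 CPM, -1.20), Wdr89 (-1.20), Gapdh (977 against 2172 CPM, -1.15) and Ahcy (-1.15). Smim19, Smim27, Erh, Ywhaq, Wdr89 and Gapdh went the opposite way in spleen. Markers of several, but not all, other cell types were lower in the minus library too. The B cell list had a median of -0.76 (-0.63 relative) over Cd74 (-0.76), H2-Aa and Ighm (0.28), and Cst3 (-0.67) of the macrophage list (median -0.52, -0.39 relative) and Klre1 (-0.81) of the NK cell list (median -0.47, -0.34 relative) were lower, while the CD4 and regulatory T cell list was at -0.23 (-0.10 relative). Summed over each list, B cell markers were 381 against 607 CPM, macrophage markers 195 against 298 CPM and melanoma markers 66.7 against 81.7 CPM. Dendritic cell markers were near level at 213 against 219 CPM. The low fibroblast with endothelial (22.5 against 17.7 CPM) and neutrophil (3.97 against 1.46 CPM) markers were higher in the minus library. With cells restricted to those with a Cd8a or Cd8b1 value and none of Cd79a, Lyz2, C1qa, Mlana or Pmel, the B cell median was 0.0078. Without naive-like cells, an alternative chosen after the data were seen, the terminally exhausted-like median was -0.20 in place of -0.53.

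Cell states were compared by clustering, with Tnfrsf9 left out. Naive-like clusters held 40.9% (38.2 to 43.7) of tumour CD137 minus cells and 21.1% (19.6 to 22.7) of tumour CD137 plus cells. The naive-like share rests on the clustering: in 8 of 14 alternative clusterings it was 26.6% to 28.0% against 12.4% to 14.2%, where a cluster led by genes such as Nrarp and Gzmm stayed unnamed. In the main clustering nearly all naive-like tumour cells lay in cluster 1, whose leading genes included the stress genes Hspa1a, Hspa1b, Maff and Klf4 beside Igfbp4 and Klf2. The terminally exhausted-like class, made of clusters 3 and 7, held 27.9% (25.4 to 30.5) of minus and 29.1% (27.4 to 30.8) of plus cells. Its clusters went opposite ways. Cluster 3, led by Spp1, Slc16a11 and Nrgn, held 13.9% (12.01 to 15.9) against 21.8% (20.3 to 23.4). Cluster 7, led by Sema6d, Mir155hg and Rgs16, held 14.0% (12.2 to 16.1) against 7.27% (6.33 to 8.30). It expressed 9 of 15 markers of exhaustion, with Havcr2 and Nr4a2 among its 10 leading genes, and 4 of 10 naive-like markers. Cells of cluster 7 had a median of 1109 and 1046 genes at mitochondrial shares of 3.91% and 3.19%, against 2047 and 1816 genes and 1.501% and 1.07% in cluster 3. Cluster 6 expressed 12 of the 15 markers of exhaustion but was led by Ccnb2 and Birc5, 2 proliferation markers, and stayed unnamed by a rule set after a first look at the clusters. It held 2.61% (1.81 to 3.65) of minus and 14.3% (13.0 to 15.6) of plus cells, 91.6% of it came from the plus library, and its median number of genes per cell was 2131 in minus and 974 in plus cells. With it, the exhausted share was 30.5% (28.0 to 33.1) against 43.3% (41.5 to 45.2). These shares are lowered in the minus library by its larger naive-like share. Among cells outside naive-like clusters the exhausted share was 47.2% (43.6 to 50.8) of minus and 36.9% (34.8 to 38.9) of plus cells, the other way round in this clustering. With cluster 6 it was 51.6% (48.0 to 55.2) and 55.0% (52.9 to 57.1). This reversal does not hold in every clustering. With seed 1 the exhausted shares were 30.5% and 43.1% and the naive-like shares 26.9% and 14.2%. There the minus library was lower outside naive-like cells too. The small difference over all cells without cluster 6 rests on the clustering: all but 2 of the alternative clusterings put the exhausted share of the minus library over 10 points lower.

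Of the other tumour clusters, cluster 4, led by Gzma, Gzmk and Klrg1, held 14.7% (12.8 to 16.8) of minus and 18.4% (17.0 to 19.9) of plus cells, and cluster 8, led by Ccl1, Penk and Xcl1, 6.50% (5.20 to 8.00) and 8.53% (7.52 to 9.64). Proliferating-like cells made up 2.30% (1.54 to 3.28) and 3.36% (2.72 to 4.10), but 3.57% to 4.20% and 5.97% to 6.25% in 8 of 14 alternative clusterings. A cluster of other cell types, which expressed 6 of 10 melanoma markers and was led by Siglech, Ly6d and MHC class II genes, made up 2.14% (1.41 to 3.10) and 3.62% (2.95 to 4.38). At resolution 1.5 there were 2 clusters of other cell types in its place, 85 tumour cells, 16 minus and 69 plus, led by Dct, Pmel and Mlana, and 51 cells led by Ly6d, Siglech and MHC class II genes. Interferon-response-like cells were 0.872% (0.436 to 1.55) and 0.578% (0.331 to 0.938), and effector-like cells 0.0792% (0.00201 to 0.441) and 0.145% (0.0394 to 0.370). The naive-like share and the naive-like list rest on the same genes and are not independent of each other.

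**Figure D2:**
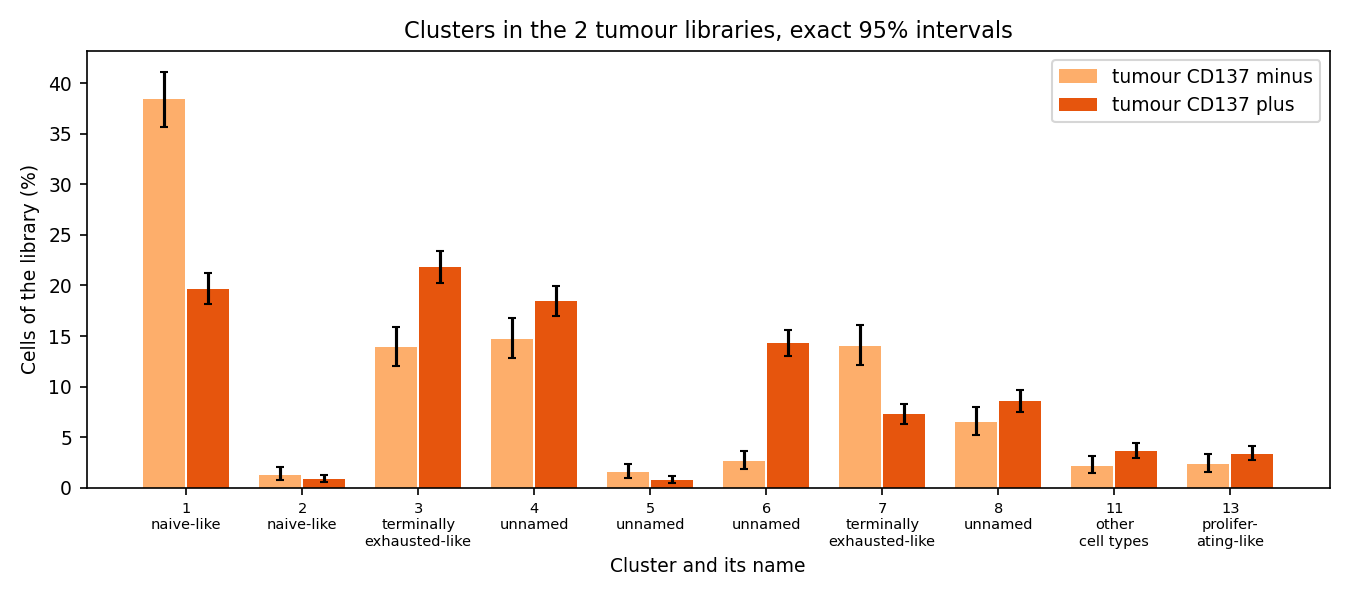
Share of cells, in percent, in each cluster that held at least 1% of a tumour library, with exact 95% binomial intervals as error bars, for tumour CD137 minus (light) and tumour CD137 plus (dark). Cluster 1, naive-like, held 38.4% of minus and 19.7% of plus cells, and cluster 6 held 2.61% and 14.3%.

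The contrast was also computed within tumour states. The clustering used exhaustion genes and the class was named by them, so a small difference in that list within the class is partly set by construction, whereas Tnfrsf9 was left out of the clustering. In terminally exhausted-like tumour cells Tnfrsf9 was 145 CPM in the minus and 803 CPM in the plus library (-2.46), and in naive-like cells 3.99 and 37.6 CPM (-2.95). The median of the terminally exhausted-like list was -0.19 within the exhausted class, where 1 of 15 genes were lower, against a median of -0.07 over all genes there. Within naive-like cells it was -0.22 against -0.18. With clusters at resolution 0.5 it was -0.15 in the exhausted class and -0.55 in naive-like cells, so within naive-like cells its size rests on the clustering. By cluster it was -0.10 in cluster 3, -0.20 in cluster 4, -0.22 in cluster 7 and -0.08 in cluster 8. The naive-like list was 0.83 in the exhausted class as a whole, with Lef1 (118 against 41.9 CPM, 1.47), and 0.49 at resolution 0.5, but 0.12 in cluster 7 and -0.82 in cluster 3, the latter over 2 measured genes. Dissociation stress genes went the same way in that class, with 5 of 17 higher and a median of 0.26, and in cluster 7, with 7 of 16 higher, 2 lower and a median of 0.31. Clusters 3 and 7 held 175 and 177 of the minus cells of this class, and 603 and 201 of its plus cells, so the class is not the same mixture in both libraries. Among the genes furthest apart within states were the granzyme gene Gzmb (7.10 against 242 CPM, -4.91) in cluster 8, the chemokine gene Ccl3 (39.9 against 153 CPM, -1.91) in cluster 4, and Smim19 (34.3 against 8.68 CPM, 1.87) in cluster 3. The Gzmb value of the minus library comes from 82 cells and lies below the 20 CPM filter, so the size of that ratio rests on few corrected counts.

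In spleen the comparison asked whether CD137 status goes with differences outside the tumour. Genes of effector T cells were lower in the spleen CD137 minus library. They included Gzma (74.1 against 290.3 CPM, -1.96), Gzmb (12.3 against 54.3 CPM, -2.06) and Gzmk (7.02 against 49.1 CPM, -2.64), which encode granzymes, Ccl4 (19.9 against 133 CPM, -2.68), and Klrg1 (4.37 against 24.7 CPM, -2.26), Cx3cr1 (6.82 against 33.2 CPM, -2.13) and Zeb2 (3.87 against 25.5 CPM, -2.45), markers and a transcription factor of terminal effector cells. Of the effector-like list, 7 of 10 genes were lower and 0 higher, with a median of -1.18, at percentile 0 of the random lists. Cytotoxic effectors had 7 of 11 lower and a median of -0.75, with Prf1 (-0.75) and Gzmm (-0.95). Memory-like genes had 5 of 8 lower and a median of -0.59, with Ccl5 (2518 against 7101 CPM, -1.50) and Il2rb (-0.89), an interleukin receptor chain. Trafficking receptors had 9 of 15 lower and a median of -0.59, among them Ccr2 (-1.55) and Itgb1 (-1.18). In the naive-like list only Igfbp4 (0.67) was higher and only Bach2 (-0.53) lower by that size, with a median of 0.09.

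The cytokine and chemokine list had 4 of 7 lower and a median of -0.59, with Ifng (-1.72). Of the terminally exhausted-like list only 5 genes were measured, and Tox (-0.61), Cxcr6 (-0.50), Gzmb and Serpina3g (-1.55) were lower. T cell lineage transcription factors had 4 of 15 lower, including Tbx21 (-0.82), and a median of -0.27. NF-kB genes had 4 of 17 lower, with Tnfaip3 (-0.86), and a median of -0.24. Inhibitory receptors were at -0.02 over 3 genes with Klrc1 (-1.77) (0.06 relative to all genes), TCR-induced factors at -0.29, proliferating-like genes at -0.16, apoptosis regulators at -0.16, MHC class I genes at -0.15 and interferon-response-like genes at 0.05 with Isg20 (0.93). Housekeeping genes were at 0.08, ribosomal proteins at 0.19, stress genes at 0.00 and glycolysis at 0.06, with Eno1 (252 against 103 CPM, 1.28) and Gapdh (521 against 306 CPM, 0.77) higher and Pfkp (-0.77) and Hk1 (-0.65) lower. The B cell list was at 0.22, and Klre1 (-1.16) of the NK cell list was lower. Over 5183 measured genes the median was -0.08 with an SD of 0.32.

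The genes furthest above 0 in spleen were Erh (70.4 against 25.9 CPM, 1.41), Eno1, Wdr89 (1.19), Ggt1 (1.07), Asnsd1 (1.04), Isg20, Ramp1 (142 against 81.1 CPM, 0.80), Cxxc5 (0.80), Slfn5 (0.80), Naa10 (0.78), Gapdh and Rgcc (0.77). Those furthest below were Ccl4, Gzmk, Zeb2, Klrg1, Cx3cr1, Gzmb, Gzma, Fasl (-1.77), which encodes Fas ligand, Klrc1 (-1.77) and Klrk1 (-1.70), NK receptor genes, Slc4a7 (-1.76) and Ifng. Effector-like cells, led by Gzma, Klrg1 and S1pr5, were 2.68% (2.08 to 3.40) of spleen minus and 9.94% (7.39 to 13.0) of spleen plus cells. Naive-like cells were 68.9% (67.0 to 70.7) and 53.9% (49.3 to 58.5). The unnamed cluster 5, led by Gzmm and Ifngas1, held 18.1% (16.6 to 19.7) and 29.4% (25.3 to 33.7). The spleen plus library was the smallest, and many of these genes lay below the level filter in the minus library. Filtering at 100 CPM brought the effector-like median to -0.41, and a pseudocount of 100 CPM brought it to -0.27.

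**Figure D3:**
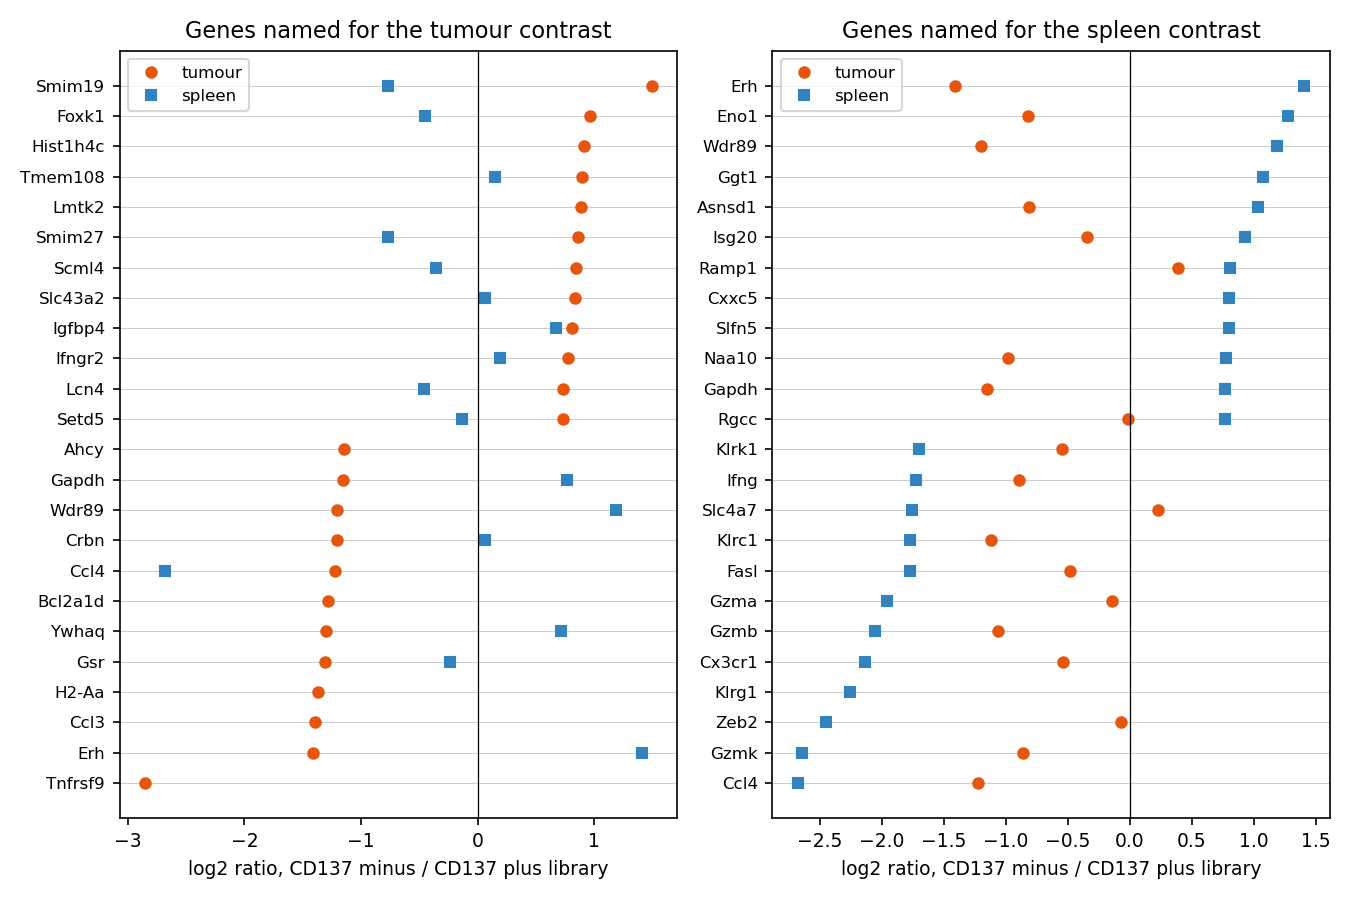
Log2 ratio of the CD137 minus to the CD137 plus library (horizontal axis) for the 24 genes named for the tumour contrast (left) and for the spleen contrast (right), each 1 library against 1 library. Circles give tumour and squares spleen, a missing symbol means that the gene was not measured there, and Erh shows values of -1.41 and 1.41 on opposite sides of 0.

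Whether the CD137 contrast depends on the tissue was described without a test. Over the 4652 genes measured in both tissues, the log2 ratios of tumour and spleen had a Pearson correlation of -0.08 and a Spearman correlation of -0.08 across genes, which are not independent replicates, and their difference had an SD of 0.41. Counting noise alone gave simulated unchanged genes an SD of 0.11 in tumour and 0.16 in spleen, against 0.27 and 0.32 observed. Such noise pulls a correlation towards 0, so its value does not show by itself that the contrast depends on the tissue. Some effector genes, chosen after their values were seen, were lower in the minus library of both tissues by at least 0.5, namely Ccl4 (-1.22 in tumour and -2.68 in spleen), Gzmb (-1.06 and -2.06), Ifng (-0.89 and -1.72), Ccl5 (-0.69 and -1.50), Tbx21 (-0.71 and -0.82) and Prf1 (-0.64 and -0.75). Igfbp4 was higher in both (0.81 and 0.67). The naive-like list stood apart mainly in tumour (0.47 against 0.09) and the effector-like list mainly in spleen (-0.18 against -1.18). In tumour 2 of 8 genes of the latter were lower by 0.5, Cx3cr1 (-0.54) and Tbx21, while Klf2 (0.43) was above 0 and Gzma (-0.14) near it. Relative to all genes 1 of these 8 was lower and 2 were higher by that size. These differences between tissues were not tested.

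**Figure D4:**
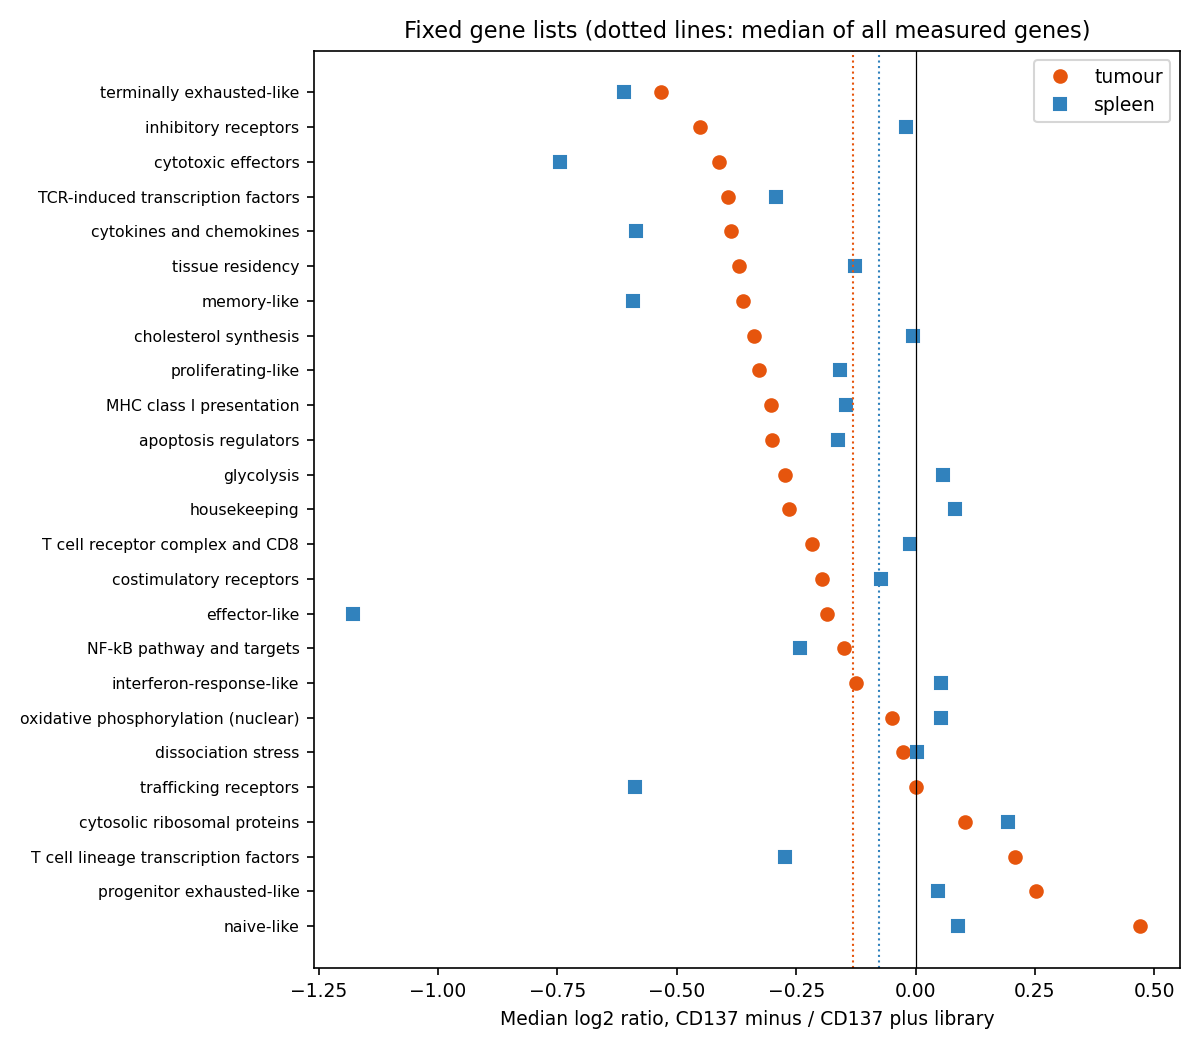
Median log2 ratio of the CD137 minus to the CD137 plus library (horizontal axis) for each fixed gene list (vertical axis), circles for tumour and squares for spleen, with dotted lines at the median of all measured genes. The naive-like list is at 0.47 in tumour and 0.09 in spleen, and the effector-like list at -0.18 and -1.18.

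Between tissues, CD137 plus CD8 T cells of the tumour carried far higher levels of inhibitory receptor and T cell receptor response genes than those of the spleen. In the CD137 plus libraries, tumour against spleen, Pdcd1 (518 against 9.73 CPM, 5.60), Tigit (412 against 17.4 CPM, 4.49), Lag3 (344 against 25.9 CPM, 3.68), Nr4a2 (1003 against 12.6 CPM, 6.21) and Rgs16 (536 against 6.08 CPM, 6.25) were higher, the last encoding a regulator of G protein signalling. Genes of naive T cells were lower, with Lef1 (113 against 371 CPM, -1.71) and Tcf7 (78.6 against 312 CPM, -1.98). In the terminally exhausted-like list 13 of 13 measured genes were higher, with a median of 2.29, and 9 of 10 inhibitory receptors, with a median of 2.74. Tissue residency genes had 6 of 7 higher and a median of 2.71, including Itga1 (2.71) and Rgs1 (4.43), TCR-induced factors 10 of 11 and 2.20, and proliferating-like genes 8 of 10 and 1.55, including Top2a (3.01). Cytokines and chemokines had a median of 1.68, with Ifng (3.74) and Xcl1 (4.03), cytotoxic effectors 1.09, with Gzmb (2.23), costimulatory receptors 1.25, with Tnfrsf4 (5.02), and NF-kB genes 0.79. Glycolysis genes had 12 of 14 higher and a median of 1.19, and cholesterol synthesis 7 of 8 and 0.92. In the naive-like list 9 of 10 genes were lower, all but Ccr7 (0.29), with a median of -1.58.

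All 14 measured dissociation stress genes were higher in the tumour plus library as well, with a median of 1.56 and Junb (1.94) and Dusp1 (2.64) among them, and this list shares Nr4a1 and Egr1 with the TCR-induced factors. Summed, the stress genes were 11412 CPM in tumour and 3626 CPM in spleen. Macrophage markers were 298 against 109 CPM, melanoma markers 81.7 against 0 CPM, NK cell markers 201 against 92.4 CPM and markers of CD4 and regulatory T cells 246 against 13.0 CPM, the last mostly from Ctla4, which exhausted CD8 T cells express too. Apoptosis regulators were at 0.34 with Bcl2 (-1.21) lower, housekeeping genes at 0.45 and ribosomal proteins at -0.22. A further 58 genes above the filter were listed at 0 in 1 of these 2 libraries and got no ratio. By the rule of size, Crem, a cAMP-responsive repressor, was highest at 6.26, followed by Rgs16, Nr4a2, Pdcd1, Litaf (5.42), Nr4a3 (5.23), Tnfrsf4, Tnfrsf9 (4.62), Tigit, Sult2b1 (4.45), Rgs1 and Nr4a1 (4.40). Lowest were G0s2 (-3.29), Slc16a5 (-3.15), Thtpa (-2.88), Dtx1 (-2.67), Art2b (-2.62), Arhgef18 (-2.46), Klhdc1 (-2.45), Chtf8 (-2.43), F2rl1 (-2.34), Tmem108 (-2.32), Ripor2 (-2.22) and S1pr5 (-2.22), an egress receptor.

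The same comparison in CD137 minus cells gave a like picture. In tumour against spleen, Pdcd1 (363 against 5.09 CPM, 5.90), Lag3 (251 against 4.17 CPM, 5.61), Tigit (254 against 6.41 CPM, 5.11), Nr4a2 (683 against 5.90 CPM, 6.63) and Ccl3 (149 against 3.46 CPM, 5.07) were higher, and Lef1 (180.4 against 487 CPM, -1.43) was lower. The terminally exhausted-like list had 11 of 11 higher and a median of 3.37, inhibitory receptors 8 of 9 and 3.04, tissue residency genes 7 of 8 and 2.80, stress genes 14 of 14 and 1.72 and glycolysis genes 10 of 15 and 0.95. In the naive-like list 8 of 10 were lower, with a median of -1.19. Memory-like genes were at 0.88, with Itgb1 (2.21). Effector-like genes were at 0.65 over 7 measured genes, with Zeb2 (2.45) and Gzma (1.40). In the plus libraries the effector-like list was at -0.22 over 10 measured genes, so these medians cover unlike sets of genes. Named by size above 0 were Rgs16 (6.73), Nr4a2, Pdcd1, Bhlhe40 (5.75), Dusp4 (5.63), Lag3, Nrgn (5.56), Mt1 (5.56), Nr4a3 (5.24), Tigit, Crem (5.08) and Ccl3. Below 0 were Art2b (-2.46), Dtx1 (-2.32), Arhgap1 (-2.19), Gpr146 (-2.16), Slc35c1 (-2.06), Ifit1bl1 (-1.93), Slfn1 (-1.92), Chtf8 (-1.91), F2rl1 (-1.86), Dgka (-1.81), a diacylglycerol kinase gene, and Cd79b (-1.79), a B cell receptor gene. Tnfrsf9 was also higher in tumour, 57.5 against 2.34 CPM (4.13). Another 17 genes, Havcr2 among them, were listed at 0 in 1 of the libraries. Across 5277 genes measured in both, the tissue log2 ratios of plus and minus cells had a Pearson correlation of 0.87 and a Spearman correlation of 0.78. Since the medians over all genes were 0.07 and 0.03, no shift was taken off in the tissue comparisons. Neutrophil, gamma-delta T cell, dendritic cell, fibroblast with endothelial and erythroid lists had at most 1 measured gene in any comparison, and their summed levels in the tumour plus library were 1.46, 15.6, 219, 17.7 and 86.9 CPM.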

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

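The share of genes with 5 or more aligned pseudogenes was planned before its result was seen, and all other tests here were chosen only after the result was seen. The differences between tissues below were not tested, since each group is 1 library.

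Among the genes named for the CD137 contrasts, 9 lay past 0.5 in opposite directions in the tissues. The log2 ratio of CD137 minus to plus in tumour less that in spleen was -2.81 for Erh, -2.39 for Wdr89, -2.10 for Eno1, -2.01 for Ywhaq, -1.92 for Gapdh, -1.85 for Asnsd1 and -1.76 for Naa10. It was 2.26 for Smim19 and 1.62 for Smim27. The opposite component used below is the log2 ratio in spleen less that in tumour, divided by 2. Gapdh and Eno1 encode glycolytic enzymes, Ywhaq a 14-3-3 adaptor protein and Naa10 an N-terminal acetyltransferase.

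Reads shared with processed pseudogenes, as an effect common to all genes with such copies, do not account for the 9 genes. Of them 22.2% had 5 or more aligned pseudogenes (exact interval 2.81 to 60.0, against 2.48% of all genes), namely Gapdh with 98 and Ywhaq with 6, too few genes for this share to decide alone. The 111 other genes with 5 or more had a median opposite component of 0.0237 relative to all genes and an SD of 0.18, against 0.96 for Gapdh and 1.01 for Ywhaq. For Erh, Eno1 and Naa10, with 1 or 2 each, the 700 other genes with 1 to 4 had a median of 0.0368 and an SD of 0.18. The 44.4% without any, Asnsd1, Smim19, Smim27 and Wdr89, have no aligned processed pseudogene to share reads with, and other kinds of copy were not counted. Of all 4551 genes, only 111 others had 5 or more and 700 others 1 to 4. A copy was thus more frequent among the 9 genes than among all genes. Lengths are those of the longest annotated transcript, and which transcript was expressed was not determined. Across 4551 genes this length and the opposite component had a Spearman correlation of -0.31. Relative to all genes the median component was -0.80 at 300 to 400 nt, -0.19 at 400 to 500 nt and 0.06 at 500 to 1000 nt. It was 0.06 at 1000 to 2000 nt and -0.04 over the 2929 genes of 2000 nt or more. The relation was not steady, and the negative correlation runs against the low values below 500 nt. By this length an effect on transcripts below 500 nt does not reach the 9 genes, but a gene read from a shorter transcript is not excluded. Of the 9 genes 77.8% were longer than 1055 nt, the limit of the shortest 10%, and Naa10 and Smim27 lay below it. These 2 genes, 1031 and 1044 nt long, went opposite ways, with opposite components of 0.88 and -0.81, whereas the 210 other genes within 10% of their lengths had a median of 0.073 relative to all genes and an SD of 0.18. Glycolysis regulated differently in the tissues would move its other genes with Gapdh and Eno1, but the 11 others had a median opposite component of 0.162 (range -0.24 to 0.22) against 1.05 for Eno1 and the value of Gapdh above. What stays open is a library effect of another kind, including one on genes read from a shorter transcript. For the 5 genes with an aligned processed pseudogene, reads shared with a copy of that single gene were not tested and stay open too. So does a tissue-dependent effect of CD137, of Cre or of the donor. For a library effect it matters that the spleen minus and tumour plus libraries also have more cells and lower totals per cell than the others.

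The median of the T cell lineage transcription factors was 0.21 in tumour and -0.27 in spleen, opposite directions, with a difference of 0.48. The B cell list had -0.76 and 0.22, a difference of -0.98, with 3 genes measured in each tissue. The tumour value was 0.0078 in CD8 cells only.

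Haemoglobin genes, which mark erythroid cells and stand outside the comparisons, had a value in 3.98% (3.28 to 4.77) of the 2766 tumour CD137 plus cells and were listed at 0 in the other libraries. A gene seen in fewer than 5 cells of a library is listed at 0, so up to 4 cells per gene are not excluded there. In the clusters with at least 90 cells of that library the share was 2.94% to 5.38%, so the signal lay in all of these clusters. No explanation was tested.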

How the results depend on the processing

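Scaling without ribosomal genes, thinned cells, leaving out naive-like cells, other cell types or the library-dominated cluster, and seeds 2 to 10 were chosen after the data were seen. So were the limit of 1.5-fold for calling a ratio moved, the bound on correlations and the choice of naive-like, effector-like and terminally exhausted-like lists as main lists. Within these limits 150 of 159 values of the main list medians, 1174 of 1215 of the others and 947 of 1080 of named genes stayed. The limit is wide for list medians. A median below 0.5 in size could cross 0 and still count, as the tumour effector-like median did without naive-like cells. The counts also hold centring and the filter on genes and mitochondrial share, which could move nothing past the limit. Of 96 named genes 50 no longer passed the size limit with a pseudocount of 100 CPM, where 85 moved, and 43 moved with 10 CPM. Without naive-like cells 2 of 24 no longer passed it. Across alternatives the tumour naive-like median ran from 0.26 to 0.60 and the terminally exhausted-like median from -0.54 to -0.20, the latter without naive-like cells. The effector-like median was 0.05 without them, on the other side of 0. The correlation between tissues ran from -0.15 to -0.01.

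A pseudocount of 100 CPM, which shrinks ratios by construction, brought the SD over genes to 0.122 in tumour, 0.119 in spleen, 0.320 between tissues in plus and 0.281 in minus cells. It brought Tnfrsf9 to -1.73 in tumour and -0.18 in spleen, the spleen effector-like median to -0.27, and between tissues the naive-like median of plus cells to -0.92 and the terminally exhausted-like median to 1.22 in plus and 1.16 in minus cells. With 10 CPM Tnfrsf9 in spleen was -1.09 and the last median 2.58. With the 100 CPM filter, which keeps fewer genes, the terminally exhausted-like median between tissues was 2.98 in plus and 5.11 in minus cells, and the spleen effector-like median -0.41. Without a filter the spleen terminally exhausted-like median was -1.25 and the B cell median between tissues in minus cells 0.10, reversed from -1.16. The tumour B cell median reversed to 0.0078 in CD8 cells only, which leaves out cells with Cd79a. The effector-like percentile between tissues in minus cells was 96.1 when matched on the share of cells and higher on expression. The cause was not tested for the percentile or the B cell medians.

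Shares of tumour cells, minus less plus, depended on the clustering. For naive-like cells the difference was 19.7 points, and 12.9 at resolution 1.5, 12.7 with seed 1 and 13.0 at the lowest of seeds 2 to 10. For terminally exhausted-like cells it was -1.18 points, and -18.3 at resolution 0.5, -11.5 at 1.5, -12.6 with seed 1, -12.3 without cell cycle genes, -12.1 in thinned cells and -17.9 at the lowest of seeds 2 to 10, where seeds 3 and 8 stayed near the main value. For proliferating-like cells it was -1.06 points, -0.531 at resolution 0.5, -2.13 at 1.5, -2.40 at the lowest of seeds 2 to 10 and -1.98 or lower in all of these seeds but 3 and 8. The cause was not tested. No paired analysis was possible because the table names no mouse per cell, so the mouse block was not run, and leaving out each mouse was not run either. A size limit of 1.0 gives no value, since no count over all genes is reported, the filter on genes and mitochondrial share removed 0 cells, and centring cannot move a correlation or an SD.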

Other observations

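All tests here were chosen only after the result was seen. Tnfrsf9, the gene of CD137, was not absent from the tumour CD137 minus library. Free RNA reaching all cells alike would give a like share in every state, but 35.5% (30.5 to 40.8) of terminally exhausted-like cells had a value against 1.36% of naive-like cells. Cells of the CD137 plus donor in the sort, as the whole source, would bring as many high cells. But 20% of those exhausted-like cells with a value held 3 or more, against 66.0% in the plus library. Transcripts from the deleted allele that still carry the 5' end are a candidate explanation, which was not tested, since the deleted exons are not given in the sources used here.

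The terminally exhausted-like list, with Gzmb, Rgs16 and Tigit its lowest members, was lower in the tumour CD137 minus library, with a median of -0.53 (-0.40 relative to all genes). The larger share of naive-like cells may account for part of it: without them the list was at -0.204 relative to all genes, and whether the rest is a difference within cells or between finer states cannot be told apart with 1 library per group. A cluster held mostly by 1 library is not the whole source, since the list was at -0.322 relative to all genes without it, and neither are cells of other types, since the median was -0.527 without them. Without both the naive-like cells and that cluster it was -0.16 relative to all genes. A difference between the libraries from their preparation stays open, as does an effect of CD137, of Cre or of the donor on the cells.

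Among 35 genes whose longest transcript is shorter than 500 nt, a set chosen after its values were seen, the median log2 ratio of minus to plus was 0.36 in tumour and -0.36 in spleen. Only 7 of them passed 0.5 in both tissues in these opposite directions, and the 27 genes of 400 to 500 nt had medians of 0.24 and -0.17. Among the furthest apart were Rps29, a ribosomal protein gene (1.08 in tumour and -1.07 in spleen), Rps28 (1.11 and -0.88), Rpl38 (0.98 and -0.99) and the mitochondrial mt-Nd4l (1.13 and -1.03). Rps29 was 1781 CPM in spleen minus, 3753 in spleen plus, 1913 in tumour minus and 903 in tumour plus.

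Of T cell receptor beta V segments, outside naive-like cells the most frequent in the tumour CD137 minus library were Trbv12-1 (17.1% of cells with a value of exactly 1 segment), Trbv4 (15.4%) and Trbv29 (10.9%). In the plus library they were Trbv12-1 (13.9%), Trbv29 (13.9%) and Trbv12-2 (11.98%). The effective number of segments was 10.9 and 11.7 there, and 14.0 and 14.8 in naive-like cells.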
